A study of Drosophila melanogaster with 10 samples.

How the data were processed

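Gene expression was measured by RNA sequencing of sorted plasmatocytes (TRIzol extraction, ribosomal RNA depletion, directional libraries per the labels, which also name polyA RNA). The labels describe 5 control and 5 infected samples. The deposited table by FlyBase gene identifier held 8 of them. Control replicate 2 and infected replicate 2 were not analysed here. A deposited table by gene name held 6 of the same libraries under matching headers, and its other 2 columns share 1 header, so they were left out. Of its genes, 8 had no identical values in the table by identifier. The treatment label gives 5 nl of buffer for controls and 50 nl for infected flies, and the design text gives 50 nl for controls.

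The deposited values are signal: gene counts that the authors multiplied by 1 factor per library and rounded to whole numbers, with whole reads recovered for 98.0% of values. The factor is not stated. The genome build is BDGP6 per the labels; the aligner, the counting tool and its treatment of overlapping genes, strand and multiple mapping are not given in the sources used here. The factor of each library, 10.1 to 22.0 units per read, was found from the values. A value was called whole reads when it lay within 0.5 units of a multiple of its factor. The table holds no zeros, so genes without a read in every library are not in it. It held 11496 genes, of which 11468 matched a symbol in the reference annotation. The depth was 1123448 to 2598869 recovered reads per library, with a median of 30 to 63 reads per gene, which limits the precision for genes of low counts.

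The plan made before the data were examined assumed raw counts, all 10 libraries and the quasi-likelihood test of edgeR. Because the files held scaled values of 8 libraries, the test became limma with a trend on log2 of the value plus 20. The authors' scaling was used without any further scaling factor. Genes with a mean value of at least 100 were tested, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Genes with a value that was not whole reads were left out of this test; that choice was made after the values were seen. It left 10951 genes, 871 of them under the mean filter. Adding 20 makes fold changes of genes with low values smaller. Lists of genes and cell type markers were fixed before the data were examined and tested with camera (correlation 0.01) when at least 5 members were tested; fry and camera with an estimated correlation were run beside it. Of 28 pathway lists 27 were tested and 15 called, 9 higher and 6 lower; of 11 marker lists 9 were tested. P values measure the spread between these libraries only. Library sizes, distances between libraries and ImpL2 were tested by exact two-sided permutation over 70 arrangements.

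Named genes were ImpL2, the 10 largest rises and 10 largest falls among called genes with a CPM of at least 10 in the higher group and no overlap between groups (454 and 259 genes qualified), up to 4 members of each pathway list with the lowest p and up to 3 members of each marker list with the highest counts. This rule was also fixed before the data were examined; how many members within these limits were named per list was set afterwards. Alternatives were RLE and upper quartile scaling, removal of mitochondrial genes before scaling, DESeq2, limma voom with quality weights and edgeR on recovered reads, no filter and a filter of CPM 5 in 5 libraries, robust variance estimation, pseudocounts of 5 and 100, a test against a fold of 1.5, a replicate block, the table by gene name, thinning to 1123448 reads, each library left out in turn, and inclusion of all genes. Of these, edgeR on recovered reads, the pseudocounts, thinning and inclusion of all genes were chosen after seeing the data. On simulated data of the same size limma recovered 75% of 2-fold and 98% of 4-fold changes, with 9 false calls among 182. The test for whole reads marked no unchanged value and found all 50 genes given a surplus, with 90.5% of their values marked. The first 2 of these outcomes were fixed in advance, because the data were built with the same factors that the test used. Error in the factors was not simulated. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.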

Results

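RNA was sequenced from plasmatocytes, the macrophage-like blood cells of Drosophila melanogaster, sorted by the fluorescence of GFP expressed under the croquemort (Crq) driver. The cells came from 10-day-old males injected with buffer (control) or with 20000 Streptococcus pneumoniae (infected). The treatment label gives 5 nl for controls and 50 nl for infected flies, and the design text gives 50 nl for controls. If the treatment label holds, effects of infection and of injected volume cannot be told apart. Of the 10 samples in the series, 8 libraries were analysed, 4 per group: control replicates 1, 3, 5 and 7 and infected replicates 1, 3, 4 and 5. Control replicate 2 and infected replicate 2 were not analysed here. The labels do not give the time between injection and sorting, nor say whether each library came from separate flies. The deposited values were read counts multiplied by 1 factor per library. Division by that factor gave 1937975 to 2598869 reads in the control libraries and 1123448 to 1413538 in the infected libraries, over 11496 genes. In 545 genes at least 1 of the 8 values was not a whole number of reads, within a tolerance of 0.5 units. These genes were left out of the tests below, except ImpL2, and their values are described at the end. All values are scaled read counts with the SD over 4 libraries, and fold changes are infected over control on a log2 scale.

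The comparison of infected with control libraries asks how transcripts in the sorted cells change after a bacterial injection. Transcripts of muscle and gut markers were abundant in these libraries too, so a change cannot be assigned to plasmatocytes alone. Genes of the immune response rose most. AttC, the antibacterial peptide Attacin-C (FBgn0041579, 2R 13393705 to 13394667), averaged 762 ± 201 in control and 27929 ± 4542 in infected libraries (log2 fold change 5.18, SE 0.18, adjusted p 2.72e-12). DptA, the peptide Diptericin A, averaged 343 ± 171 in control and 10124 ± 2158 in infected libraries (log2 fold change 4.96, SE 0.31, adjusted p 5.76e-09). The other large rises were TotX (4.74), AttA (4.62), AttB (4.61), TotB (4.60), DptB (4.59), edin (4.52), TotF (4.41) and IM18 (4.19), with adjusted p from 9.72e-12 to 5.94e-09. PPO1, a prophenoloxidase of crystal cells (FBgn0283437, 2R 17887220 to 17889973), averaged 5454 ± 1447 in control and 810 ± 407 in infected libraries (log2 fold change -2.81, SE 0.28, adjusted p 2.72e-06). The other large falls were in the eggshell genes Cp38 (-2.28), dec (-2.21) and Cp15 (-1.97), the yolk gene Yp2 (-2.04), the digestive proteases Jon25Bi (-1.98) and Jon99Ciii (-1.86), wrapper (-1.93), PPO2 (-1.81) and CG12057 (-1.75), with adjusted p up to 0.0274. Of 10080 genes tested with limma, 805 differed at an adjusted p under 0.05, 523 higher and 282 lower in infected libraries. Among them 269 rose and 94 fell by more than 2-fold. The groups did not overlap in 1452 genes, 14.4% of those tested, where chance gives 2.86%, and 733 of the 805 were among these. With upper quartile scaling 844 genes differed, of which 53.9% were higher, against 65.0% with the authors' scaling alone. The count was 485 without control replicate 3, 501 without control replicate 7 and 487 without infected replicate 4, and the calls of Yp2 and Cp15 ended without control replicate 5 (adjusted p 0.0956 and 0.0817), control replicate 7 (0.0841 and 0.0767) or infected replicate 4 (0.0831 and 0.0624); without infected replicate 3 their log2 fold changes were -1.30 and -1.33.

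**Figure D1:**
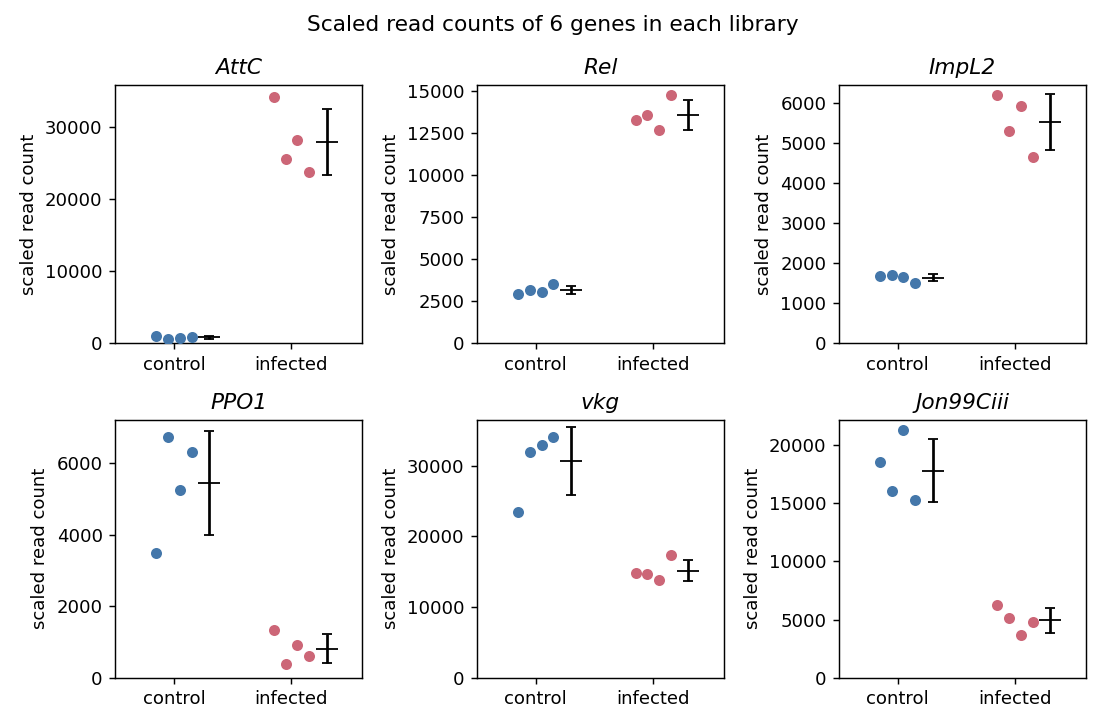
Scaled read counts (y axis, from 0) of 6 genes in the 4 control (blue) and 4 infected (red) libraries, with the mean and SD in black. AttC, Rel and ImpL2 were higher and PPO1, vkg and Jon99Ciii lower in every infected library than in every control library; 3 of the 8 ImpL2 values were not whole reads.

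Antimicrobial peptides and Bomanins, small secreted peptides of the humoral response, rose as a list: 23 of 28 tested members were higher and none lower over all genes tested, with a median log2 fold change of 2.01 (camera adjusted p 2.68e-43). Adjusted over the list alone, 23 were higher and 1 lower. Dro, the peptide Drosocin, averaged 1984 ± 240 in control and 18288 ± 2541 in infected libraries (log2 fold change 3.19, SE 0.14, adjusted p 4.66e-11). The values of Dro differed between the 2 deposited tables, and reads of AttA and AttB, which are near-identical copies, could not be separated with certainty. Among components of the Imd and Toll pathways, which control these peptides, 10 of 21 rose and none fell (median 0.50, adjusted p 1.77e-12), and 11 rose adjusted over the list alone. The other 12 of the 33 members held values that were not whole reads. Rel, the NF-kappaB factor Relish of the Imd pathway, averaged 3140 ± 243 in control and 13549 ± 873 in infected libraries (log2 fold change 2.10, SE 0.12, adjusted p 2.25e-09). The peptidoglycan recognition genes PGRP-SC2 (2.55), PGRP-SB1 (2.31) and PGRP-SD (2.36) rose as well, with adjusted p from 3.25e-08 to 8.26e-08. Of 5 Turandot stress peptides tested, TotB, TotX and TotF rose and TotZ did not pass the test (log2 fold change 0.72, adjusted p 0.266; list adjusted p 9.71e-10).

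Of 16 heat shock genes 10 were higher, and 11 adjusted over the list alone (median 0.84, camera adjusted p 4.33e-11). Hsp22, a mitochondrial small heat shock protein, averaged 646 ± 129 in control and 2794 ± 731 in infected libraries (log2 fold change 2.06, SE 0.21, adjusted p 2.71e-06). Hsp70Ab (2.31, adjusted p 1.09e-06), 1 of several near-identical Hsp70 copies, Hsp68 (1.70, 4.08e-06) and Hsp26 (1.06, 2.45e-04) rose too. Of 19 genes of the unfolded protein response and secretion 11 were higher, and 12 adjusted over the list alone (median 0.55, adjusted p 9.00e-10; not called with an estimated correlation, 0.134). In 8 of these 11 genes infected replicates 1 and 4 were both above infected replicates 3 and 5. TRAM was at 7766 and 8182 against 2503 and 3945. Chance gives 16.7% for 1 gene, but genes of a list can vary together and the pair was not part of the plan. This limit holds wherever the pair is given below. The same order held in 5 of 23 called antimicrobial peptides and Bomanins, 2 of 10 Imd and Toll genes, 2 of 10 heat shock genes and 0 of 3 Turandot genes. The 11 called genes of the unfolded protein response and secretion included the endoplasmic reticulum chaperones Gp93 (log2 fold change 1.27, adjusted p 7.78e-05) and Hsc70-3 (log2 fold change 0.88, adjusted p 4.54e-04). CaBP1 (log2 fold change 1.04, adjusted p 2.45e-04) and TRAM (log2 fold change 1.80, adjusted p 2.91e-04) were among them too. In the JAK/STAT list, 2 of 7 rose (adjusted p 0.0132, estimated correlation 0.124): the feedback inhibitor Socs36E (log2 fold change 2.01, adjusted p 6.54e-08) and et (log2 fold change 1.39, adjusted p 0.00162). Infected replicates 1 and 4 were both above infected replicates 3 and 5 for et (3789 and 3063 against 1427 and 1539), but not for Socs36E. In the JNK and damage response list, 3 of 8 rose (adjusted p 0.0132; estimated correlation 0.124; 6 of 14 members untested): the transcription factor Ets21C (log2 fold change 2.37, adjusted p 1.53e-07), Gadd45 (log2 fold change 1.77, adjusted p 1.37e-04) and the matrix metalloproteinase Mmp1 (log2 fold change 0.93, adjusted p 0.00468). Of 8 iron handling genes, the transferrins Tsf3 (log2 fold change 1.98, adjusted p 6.82e-06) and Tsf1 (log2 fold change 0.74, adjusted p 0.00601) rose, and 4 rose adjusted over the list alone (list adjusted p 0.00255; estimated correlation 0.124). Both were higher in infected replicates 1 and 4 than in 3 and 5, with Tsf1 at 75581 and 81354 against 59758 and 61464. With a correlation estimated from the data in place of the preset 0.01, the rises of antimicrobial peptides (adjusted p 0.00725), Imd and Toll components (0.0303), Turandot peptides (0.0228) and heat shock genes (0.00725) were called.

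**Figure D2:**
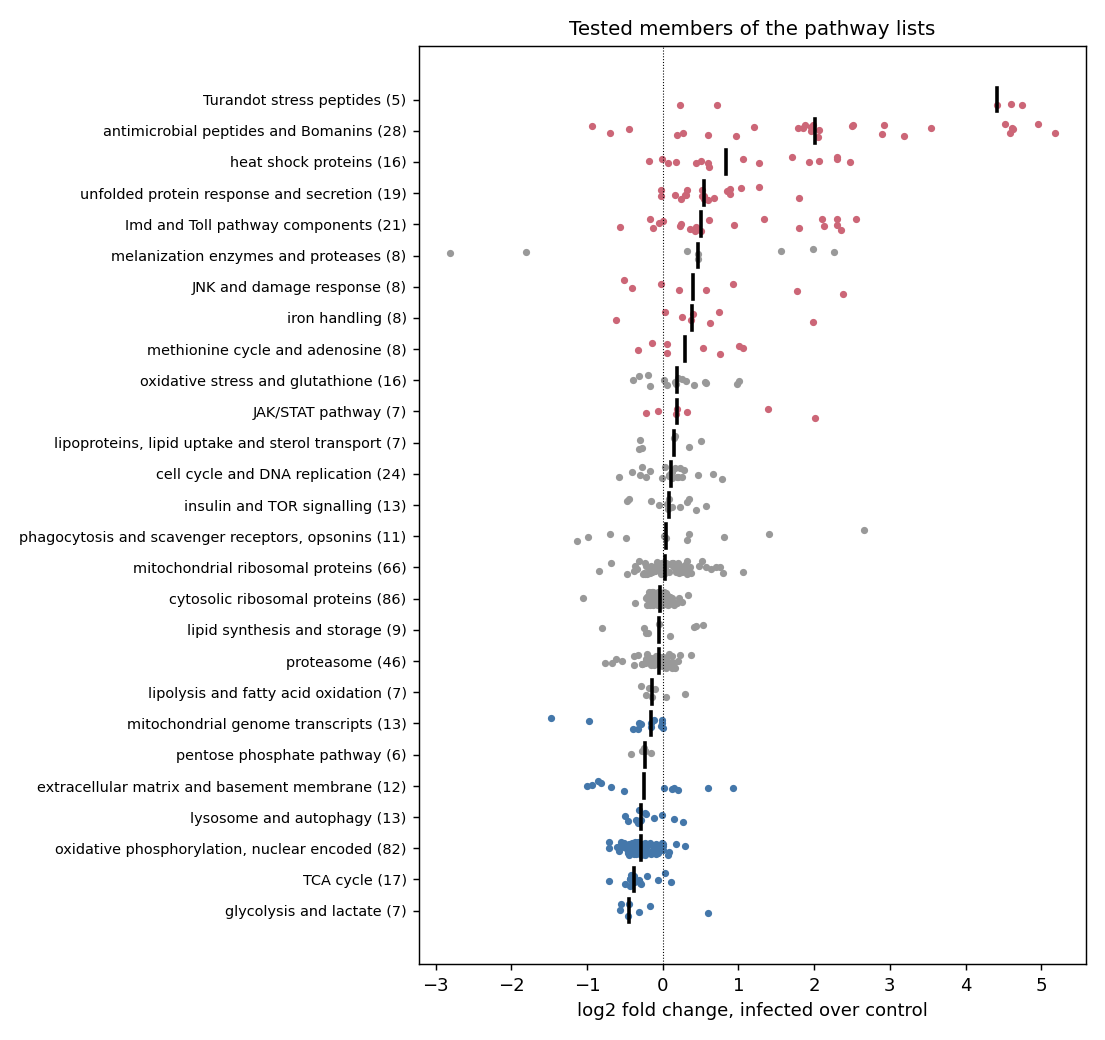
Log2 fold change, infected over control (x axis), of each tested member of the 27 pathway lists tested, with the median as a black bar and the number of members in brackets. Red lists were called higher, blue lists lower and grey lists neither by camera; antimicrobial peptides had a median of 2.01.

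ImpL2, a secreted protein that binds insulin-like peptides, is named in the title of the series. The comparison asks whether its transcript changes in cells sorted from infected flies. ImpL2 (FBgn0001257, build BDGP6, 3L 4224006 to 4236147, minus strand) averaged 1630 ± 91.5 (SD, n = 4) in control and 5514 ± 699 in infected libraries. The log2 fold change was 1.74 (SE 0.13, adjusted p 3.72e-07 in a limma fit of all 10606 genes), and every infected library was above every control library. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow. Of its 8 values, 3 were not whole reads: control replicate 1, control replicate 5 and infected replicate 4, which lay 3.69, -2.65 and 3.09 units from the nearest multiple of 1 read. With these 3 values treated as missing, the log2 fold change was 1.73 (adjusted p 5.3e-05).

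Insulin and TOR signalling, the pathway that ImpL2 antagonises, was not called as a list (camera adjusted p 0.179), and 8 of its 21 members were untested because a value was not whole reads. With these 8 members included the list was called higher (adjusted p 2.81e-05). Of 13 tested members 1 rose, and 2 adjusted over the list alone: Thor, the translation inhibitor 4E-BP, averaged 2503 ± 354 in control and 3690 ± 240 in infected libraries (log2 fold change 0.56, SE 0.14, adjusted p 0.0184). Pi3K92E (0.44, adjusted p 0.0747), Akt (0.35, 0.164) and Myc (0.32, 0.171) did not pass the test; Pi3K92E passed with voom (0.0414), edgeR (0.0498) or all genes (0.0453). The call of Thor ended without control replicate 1 (adjusted p 0.0576) and without control replicate 3 (0.0926).

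Lower transcripts of energy metabolism were found in a few members of 3 lists, none of which was called with an estimated correlation. In the same libraries the muscle and gut marker lists were lower too, with medians of -0.64 and -0.73. Of 17 TCA cycle genes 3 fell and 9 fell adjusted over the list alone (median -0.37, camera adjusted p 1.81e-05; estimated correlation 0.238). Idh3g, a subunit of isocitrate dehydrogenase, averaged 5786 ± 484 in control and 3518 ± 288 in infected libraries (log2 fold change -0.71, SE 0.13, adjusted p 0.00157). Pdha (log2 fold change -0.44, adjusted p 0.0405) and Idh3a (log2 fold change -0.43, adjusted p 0.0495) fell too, but the call of Pdha ended when any 1 of the 8 libraries was left out (adjusted p up to 0.106, without control replicate 3), and that of Idh3a when any 1 library except infected replicate 3 was left out (up to 0.136, without control replicate 7). Of 82 nuclear genes of oxidative phosphorylation 3 fell, and 1 adjusted over the list alone (median -0.29, adjusted p 1.19e-07; estimated correlation 0.162): ATPsynC (log2 fold change -0.55, adjusted p 0.0129), COX6B (log2 fold change -0.55, adjusted p 0.0245) and ND-B14.5A (log2 fold change -0.70, adjusted p 0.0374). The call of ATPsynC ended without infected replicate 4 (0.055). That of COX6B ended without control replicate 1 (0.0697), control replicate 7 (0.0979), infected replicate 1 (0.0612) or infected replicate 4 (0.0763), and that of ND-B14.5A without control replicate 5 (0.112), control replicate 7 (0.118), infected replicate 1 (0.102) or infected replicate 4 (0.074). Of 13 mitochondrially encoded transcripts, mt:ND3 (log2 fold change -1.47, adjusted p 2.50e-04) and mt:ND4L (log2 fold change -0.97, adjusted p 0.017) fell (list adjusted p 0.0269; estimated correlation 0.522). The list was not called without control replicate 7 (0.145), infected replicate 1 (0.136) or infected replicate 3 (0.118). Nor was the list called by fry (0.225) or with the replicate block on libraries 1, 3 and 5 (0.0612). The call of mt:ND4L ended without control replicate 1 (0.0521) or control replicate 7 (0.0741).

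Of 7 tested members of the glycolysis and lactate list Gapdh2 (log2 fold change -0.56, adjusted p 0.0121) and PyK (log2 fold change -0.55, adjusted p 0.0247) fell, Pfrx did not pass the test (-0.46, adjusted p 0.105), and 4 fell adjusted over the list alone (camera adjusted p 0.0132, estimated correlation 0.172). The other 10 of the 17 members held values that were not whole reads, and with them the list was called higher (adjusted p 0.000367). The call of Gapdh2 ended without control replicate 7 (0.0508), that of PyK without control replicate 7 (0.0691) or infected replicate 1 (0.0626), and that of the list without infected replicate 3 (0.0764). Pfrx passed without control replicate 1 (0.0494). Lipoproteins, lipid uptake and sterol transport, also named in the series title, could be tested in 7 of 20 members; none passed (adjusted p 0.828), with Hr96 at 0.51 (adjusted p 0.163) and Npc1a at -0.31 (0.242). With the 13 other members included, that list was called higher (adjusted p 1.9e-05). Lipid synthesis and storage could be tested in 9 of 20 members (adjusted p 0.832); the acyl-CoA synthetase gene bgm fell (-0.80, adjusted p 0.00981), and Agpat3 (0.54, 0.0924) passed without infected replicate 3 (0.0108), with voom (0.0324), with edgeR (0.0446) and with edgeR on thinned reads (0.0218). With the 11 other members it was called higher (adjusted p 1.98e-05). In lipolysis and fatty acid oxidation none of 7 tested genes differed (adjusted p 0.468), nor did any of 6 in the pentose phosphate pathway (0.0785), a list called lower without control replicate 3 (0.0427), infected replicate 1 (0.0394) or infected replicate 4 (0.0198), and on libraries 1, 3 and 5 with the replicate block (0.0226) or without it (0.0259).

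In the methionine cycle and adenosine list 3 of 8 tested genes rose: Cth (log2 fold change 1.06, adjusted p 0.0022), Gnmt (log2 fold change 0.76, adjusted p 0.00429) and Nmdmc (log2 fold change 1.001, adjusted p 0.00886). Nmdmc (3R 9042508 to 9050555) encloses Rel (3R 9044183 to 9047977) on the same strand. Nmdmc averaged 362 in control and 735 in infected libraries, against 3140 and 13549 for Rel. How reads of overlapping genes were counted is not known, so the rise of Nmdmc cannot be told apart from that of Rel. The list was called higher (camera adjusted p 0.0295), but not with an estimated correlation (0.189) or without infected replicate 4 (0.066). Nor was it called with the replicate block on libraries 1, 3 and 5 (0.0725), and 7 of its 15 members were untested. None of 16 tested oxidative stress and glutathione genes differed (list adjusted p 0.147), but 9 of the 26 members held values that were not whole reads, and with them the list was called higher (adjusted p 2.38e-04). Among the tested genes the glutathione transferase GstE1 (0.98, adjusted p 0.0528) passed without infected replicate 3 (0.0211) or infected replicate 5 (0.0384), and also with DESeq2 (0.0236), edgeR (0.0256), robust variances (0.0484) or all genes (0.0432). In the lysosome and autophagy list 1 of 13 tested genes fell, the proton pump subunit Vha16-1 (log2 fold change -0.50, adjusted p 0.0289), and the list was called lower (0.0132; estimated correlation 0.204). The call of Vha16-1 ended when any 1 library except infected replicates 3 and 5 was left out (adjusted p up to 0.0828, without infected replicate 1). With its 13 members whose values were not whole reads, the list was not called (adjusted p 0.428). None of 24 cell cycle, 66 mitochondrial ribosomal and 46 proteasome genes differed, and those lists were not called (adjusted p 0.656, 0.526 and 0.147). Of 86 cytosolic ribosomal protein genes RpS6 fell (-1.05, adjusted p 0.0173), a call that ended without control replicate 7 (0.0665); the list was not called (0.275) except without control replicate 5 (0.0191). Only 2 histone genes of near-identical copies could be tested, too few for a list test. His1:CG33813 (1.74, adjusted p 0.0189) was called higher, but not without control replicate 3 (0.0575), infected replicate 1 (0.0682) or infected replicate 4 (0.0594). His1:CG31617 (1.49, 0.0405) was called higher, a call that ended when any 1 library except control replicate 5 and infected replicates 3 and 5 was left out (up to 0.152, without infected replicate 4).

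Of 12 tested extracellular matrix genes 5 fell, 1 rose and 6 did not pass the test, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p 0.0295; estimated correlation 0.476). vkg, a collagen IV chain, averaged 30584 ± 4814 in control and 15151 ± 1511 in infected libraries (log2 fold change -1.003, SE 0.14, adjusted p 1.66e-04). Col4a1, the other collagen IV chain, averaged 46542 ± 7968 in control and 25501 ± 3715 in infected libraries (log2 fold change -0.86, SE 0.15, adjusted p 0.00145). SPARC (log2 fold change -0.93, adjusted p 3.30e-04) and Ppn (log2 fold change -0.82, adjusted p 0.00243) fell as well. The list was not called without control replicate 5 (adjusted p 0.127) or infected replicate 3 (0.149), nor by fry (0.113). Of 11 tested genes of phagocytosis, 3 rose and 3 fell (adjusted p 0.405; estimated correlation 0.597). Another 13 of the 26 members held values that were not whole reads, and with all genes the list was called higher (adjusted p 2.17e-05), as it was by fry on the tested genes (0.0257). Tep2, a thioester protein that opsonises bacteria, averaged 6972 ± 1800 in control and 43718 ± 6911 in infected libraries (log2 fold change 2.66, SE 0.17, adjusted p 5.77e-09). The integrin scb (log2 fold change 1.41, adjusted p 1.44e-06) and NimB1 (log2 fold change 0.81, adjusted p 0.00936) rose, and the scavenger receptor Sr-CI (log2 fold change -1.13, adjusted p 1.94e-04) fell. In the melanization list 3 of 8 rose and 2 fell, among them the protease Sp7 (log2 fold change 1.99, adjusted p 6.00e-07) and the serpin Spn28Dc (log2 fold change 2.26, adjusted p 4.56e-06), against lower PPO2 (log2 fold change -1.81, adjusted p 1.01e-06) and PPO1; the list was not called (0.0633) except without control replicate 3 (0.0427), control replicate 5 (0.0437) or control replicate 7 (0.0462). In 4 of the 5 called melanization genes infected replicates 1 and 4 were both above infected replicates 3 and 5, where chance gives 16.7%: Sp7 was at 2715 and 2811 against 1976 and 1886, and PPO1 at 1326 and 923 against 395 and 597. With its 3 members whose values were not whole reads the melanization list was called higher (adjusted p 9.44e-04).

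Marker lists of the sorted cell type and of other cells were compared in the same way. All 5 tested plasmatocyte markers were lower: Ppn, Col4a1 and vkg, which are also on the extracellular matrix list, and Sr-CI and NimB4, which are also on the phagocytosis list (median -0.86, camera adjusted p 1.26e-07; estimated correlation 0.0619), but 10 of the 15 markers, Hml among them, held values that were not whole reads, and with them the list was not called (adjusted p 0.673). Of 6 crystal cell markers PPO1 and PPO2 were lower, 3 adjusted over the list alone (adjusted p 1.80e-04; estimated correlation 0.0619), while numb (-0.07, adjusted p 0.837) and peb (-0.19, 0.491) did not differ beyond the spread. Of 12 gut markers 8 were lower (median -0.73, adjusted p 2.23e-08; estimated correlation 0.102), while the most abundant, Amy-p (0.28, 0.467), Amy-d (0.29, 0.343) and Mal-A1 (-0.10, 0.808), did not pass the test. Mal-A1 averaged 22325 ± 4756 in control libraries, so transcripts of digestive enzymes were abundant in these libraries. The muscle gene sls averaged 125994 in control libraries, against 65747.5 for Ppn and 46542 for Col4a1, both plasmatocyte markers. These counts are not corrected for transcript length. The gene sls (3L 2039681 to 2115611) is longer than Col4a1 (2L 5029609 to 5037279). The counts therefore do not show whether muscle RNA exceeded plasmatocyte RNA. Which cells the changes described above came from was not tested. Of 21 muscle markers 9 were lower (median -0.64, adjusted p 1.85e-09; estimated correlation 0.303), and the most abundant did not pass: sls (-0.38, 0.406), bt (-0.64, 0.0679), which passed without control replicate 1 (0.0304), with DESeq2 (0.0184), upper quartile scaling (0.0388) or mitochondrial genes left out of the scaling (0.0317), and Strn-Mlck (-0.47, 0.146). Control replicate 5 stood above the other control libraries in all 3: sls was at 211824 against 78210 to 111844, bt at 121170 against 53531 to 70193 and Strn-Mlck at 34092 against 16379 to 19213. Without it the muscle list was still called lower (adjusted p 2.35e-06). With all 8 libraries fry did not call the muscle list (adjusted p 0.0712). Of 6 tested fat body markers 3 yolk genes fell, Yp1 (log2 fold change -2.13, adjusted p 0.0431), Yp2 and Yp3 (log2 fold change -1.40, adjusted p 0.0239), and 1 rose; the list was not called (0.0734) except without infected replicate 1 (0.0114) or infected replicate 5 (0.0276), with the replicate block on libraries 1, 3 and 5 (0.0104) or with CPM of at least 5 in at least 5 libraries (0.0432). The other 8 of 14 fat body markers held values that were not whole reads, and with them the list was called higher (adjusted p 0.0107). The labels describe male flies, so the falls of the yolk genes cannot be assigned to the fat body. In infected replicates 1, 3, 4 and 5 Yp1 was at 2736, 110, 608 and 2040. Yp2, Yp3 and the eggshell gene Cp15 followed the same order, with Cp15 at 547, 44, 168 and 481, while the eggshell genes Cp38 and dec did not. The calls of Yp1 and Yp3 ended without control replicate 5 (0.131 and 0.0889), control replicate 7 (0.116 and 0.0822) or infected replicate 4 (0.107 and 0.074), and that of Yp1 also without control replicate 1 (0.0619) or control replicate 3 (0.0699); without infected replicate 3 Yp1 fell by 1.24. The testis and accessory gland list (0.711, with Acp36DE at 0.13, 0.807) and the nephrocyte list (0.105) were not called. Nor were the neuron list (0.104), except without infected replicate 3 (0.0284), and the photoreceptor list (0.0734, with Arr1 at 0.15, 0.623), except without control replicate 5 (0.0265), infected replicate 1 (0.0434) or infected replicate 5 (0.0444). Of 3 tested lamellocyte markers mys rose (0.73, 0.0116), cher (0.46, 0.0662) passed without control replicate 5 (0.00886), with voom (0.00626) and in the table by gene name (0.0181), and msn did not (0.20, 0.42); with 2 more members whose values were not whole reads, that list was called higher (adjusted p 0.0107). Of 4 cuticle markers Cpr72Ec rose (0.86, 0.00192).

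Infected libraries held fewer reads. They averaged 1253367 ± 122696 recovered reads (SD, n = 4) and control libraries 2220395 ± 299388, so infected libraries had 56.4% of the control reads (exact permutation p 0.0286, two-sided, the smallest that 4 against 4 allow). The deposited totals, after the scaling, were 25974981 ± 1165150 in infected and 25417898 ± 658074 in control libraries (exact permutation p 0.429). Infected libraries lay farther from each other than control libraries did: the mean distance in log2 CPM was 63.8 among infected and 49.6 among control libraries, a difference of 14.1 that did not pass the test (exact permutation p 0.0571). The difference was 14.4 without control replicate 1 and 17.6 without control replicate 5 (exact permutation p 0.0286 each). It did not pass without control replicate 3 or 7 (exact permutation p 0.0571 each), infected replicate 1 (0.2), 3 (0.229), 4 or 5 (0.143 each). Nor did it pass in the 500 most abundant genes (1.97, exact permutation p 0.2), with a prior count of 10 (10.6, exact p 0.0857) or with all libraries thinned to the same number of reads (4.76, exact p 0.286).

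Values that were not whole reads were concentrated in the infected libraries, in particular gene lists and at the start of the table. Of 91968 values 1811, in 545 of 11496 genes, lay more than 0.5 units from a multiple of 1 read: 1315 infected values (2.86%) and 496 control values (1.08%). They were held by 10 of 15 plasmatocyte markers (66.7%), 13 of 20 lipoprotein and lipid uptake genes (65%), 10 of 17 glycolysis genes (58.8%), 8 of 14 fat body markers (57.1%) and 11 of 20 lipid synthesis genes (55%). The shares were 50% in phagocytosis, 48.1% in lysosome, 46.7% in methionine cycle, 42.9% in JNK, 41.7% in lipolysis, 38.1% in insulin and TOR, 36.4% in Imd and Toll, 34.6% in oxidative stress and 29.4% in extracellular matrix genes. Fisher's exact test gave adjusted p from 1.18e-11 to 0.00252 for these 14 lists, 0.0342 for melanization (27.3%) and 0.0722 for lamellocyte markers (33.3%). They were also concentrated by position: 63 of the first 130 genes of the table held one (48.5%), against 482 of the 11366 later genes (4.24%). Among the later genes alone, Fisher's exact test gave adjusted p from 1.03e-12 to 0.0203 for the same lists, a test chosen after the values were seen. No unfolded protein response, oxidative phosphorylation, mitochondrial ribosomal, proteasome, Turandot or crystal cell marker gene held one, and 1 of 89 cytosolic ribosomal protein genes did. Of 526 such genes with enough reads, 358 (68.1%) differed in a limma fit of all genes, 344 higher and 14 lower, against 9.35% of whole-read genes. All 4 infected values were affected in 160 genes, of which 158 were higher in infected libraries, and all 4 control values in 16 genes. In 53 of the 160 genes, subtracting 1 round amount made all 4 infected values whole reads: 2500 in 35 genes, among them foxo, imd, bsk, Atg18a, CecA1 and Npc2h, 5000 in 11, among them fabp and Pglym78, 750 in 3, 25000 in 2 (Gapdh1 and Hml) and 50000 in 2 (Desat1 and FASN1). Of the amounts from 1 to 60000 that are not multiples of 250, none did so in more than 1 gene. Changes of single lipoprotein, lipid synthesis, glycolysis and plasmatocyte marker genes that rest on such values are not given here. With these genes included, 1300 of 10606 genes differed, 940 higher and 360 lower.

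**Figure D3:**
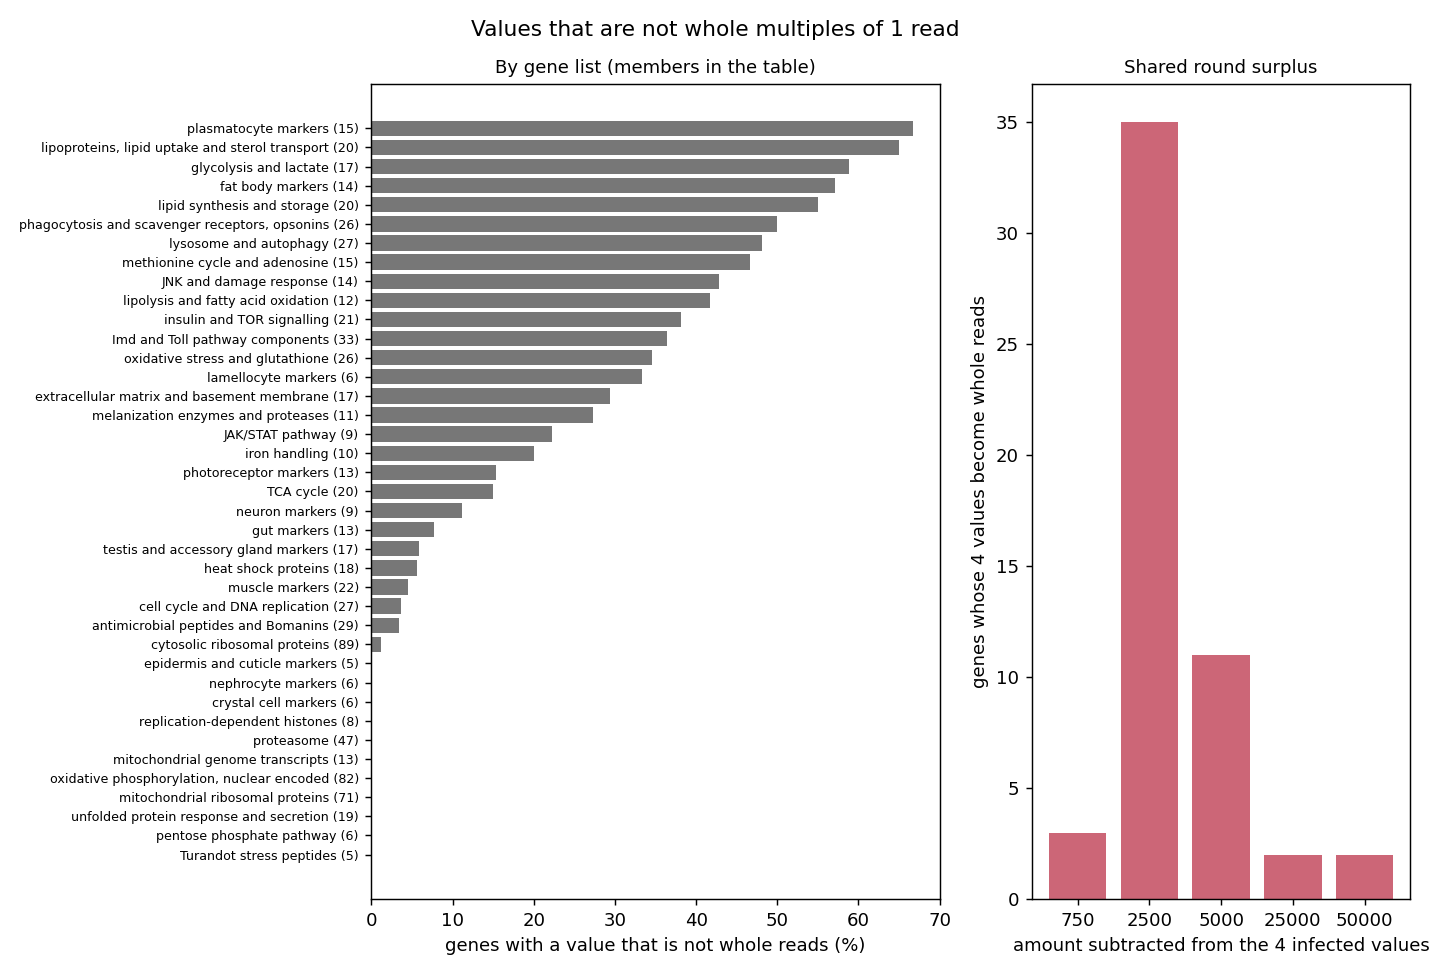
Left, the percent of genes in each list (x axis; members in brackets) with a value that is not a whole number of reads, from 0 to 66.7% in plasmatocyte markers. Right, the number of genes (y axis) whose 4 infected values became whole reads when the amount on the x axis was subtracted: 35 genes at 2500 and 11 at 5000.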

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

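All tests of explanations in this part were chosen after the results were seen. Among 196 groups of 4 values, 7 held a library far from the other 3 of its group, where chance gives about 1 in 20 groups, 9.8 here; 5 of the 7 were in control replicate 5. Control replicate 5 had scaled read counts of 3827 for bgm (others 2614 to 2702), 3072 for Gnmt (2030 to 2081), 9638 for Tep2 (5878 to 6479), 24464 for ATPsynC (18815 to 19616) and 34092 for Strn-Mlck (16379 to 19213). Infected replicate 1 had 2378 for bgm (others 1405 to 1559), and infected replicate 3 had 593 for Nmdmc (770 to 800).

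The values that are not whole reads were weighed first. Rounding is argued against, since 93.5% of these values lay more than 1 unit from the nearest multiple, against 93.6% for values spread evenly. A misjudged factor could give that spread in genes with many reads, so this share does not weigh on it. Such a factor would move all genes with many reads. Yet only 1 of 22 muscle markers held such a value, and the abundant sls held none, which argues against it. A second sequencing run added with another factor would reach every abundant gene, yet 98.9% of ribosomal protein genes held 8 whole values; and reads split between near-identical genes are argued against by 0 of 88 off-step values in such genes. A fixed amount added to the 4 infected values is a candidate explanation for the 53 genes that share a round surplus, but it cannot account for the 98 genes that no amount from 1 to 60000 made whole. How the values arose is not known from the files, no biological explanation was tested for departures from whole reads, and the authors' processing steps or unscaled counts would be needed to settle it.

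Lower markers of other cells were weighed second. Fewer crystal cells in the sort, with PPO1 and PPO2 found only in them, would lower both alike, but the log2 ratio of PPO1 to PPO2 went from 0.34 to -0.67 (exact permutation p 0.0286); fewer crystal cells stay open if other cells also express PPO2. An equal fall of all gut markers is argued against. The 3 most abundant had a median log2 fold change of 0.28, while the list had -0.73 (interval -1.28 to -0.22). Their values were 0.28 (SE 0.20) for Amy-p, 0.29 (SE 0.17) for its near-identical copy Amy-d and -0.10 (SE 0.17) for Mal-A1. None of the 3 passed the test, so less gut RNA with other changes in these genes stays open. The median of the testis list lay 0.62 above that of the muscle list (interval 0.34 to 0.85). Both intervals resample genes and leave out the spread between libraries. They do not settle whether RNA of all other tissues was lower. A sort for GFP should remove most of these cells, but transcripts of muscle and gut were abundant in these libraries. A response of the tissues themselves to infection stays open and untested, as does less RNA of muscle alone.

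The difference in depth was weighed last. With every library thinned to the same number of reads and tested with edgeR, which tested 8400 genes, 673 of the 805 genes called by limma were called, which argues against fewer infected reads as the cause of most calls. Both the test and the depth changed there; edgeR without thinning called 772 of the 805. Chance is argued against for the number of genes. Of the 35 splits of the 8 libraries into 4 and 4, only the real split reached its 805, and the highest other gave 0. That share, 1 of 35, is the smallest this test can give. Every other split mixes infected and control libraries on each side, which widens the spread and lowers its calls. For the number of lists, 1 of 35 splits reached the real 15, with the highest other at 13. The real count of lists was 12 to 17 with 1 library left out (12 without infected replicate 3) and 4 with an estimated correlation. Splits were not run under these settings, so chance is not excluded for the number of lists.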

How the results depend on the processing

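The alternatives chosen after seeing the data were edgeR on recovered reads, the pseudocounts, thinning, inclusion of genes with values that are not whole reads, missing ImpL2 values and deposited totals; the others were planned. ImpL2 was higher and past the threshold under every alternative run, with log2 fold changes from 1.66 to 1.82 (1.68 to 1.82 with 1 library left out). For the 74 called genes named, 1626 of 1810 alternatives gave the same call, 184 fell short and 0 reversed; for uncalled genes 495 of 523 were the same, 21 passed and 7 reversed. For lists 469 of 538 were the same, 29 fell short, 23 passed and 17 reversed. The number of genes that differed was 345 with a replicate block and 320 on the same 6 libraries unblocked. The correlations of same-numbered libraries were -0.03, -0.003 and -0.01, within the -0.15 to 0.18 of differently numbered libraries. No effect shared by equal numbers was seen, and the labels do not say whether the numbers pair libraries. The number of genes that differed was 124 against a fold of 1.5, a stricter question, and 370 in the table by gene name with 6 libraries. It was 485 to 1037 with 1 library left out (1037 without infected replicate 3, a rise whose cause was not tested). With all genes it was 1300, of which 358 were genes added. The rest of the rise was in whole-read genes, whose fold changes are the same in both fits. Pi3K92E, for 1, kept 0.44 while its adjusted p went from 0.0747 to 0.0453. Only the shared variance estimate and the adjustment over genes differ between these fits, and their shares were not tested. Of 27 lists 4 were called with an estimated correlation, 12 to 17 with 1 library left out. The difference in reads was -967028, -1061170 to -840870 with 1 library left out, and 557083 in deposited totals, which the authors' scaling had made nearly equal. The difference in distance was 11.7 to 17.6 with 1 library left out, past the threshold at 14.4 and 17.6. Where not stated, the cause was not tested.

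Including genes with values that are not whole reads turned the direction of glycolysis (adjusted p 0.000367), lipid synthesis (1.98e-05), lipolysis (0.471), lysosome (0.428), plasmatocyte markers (0.673) and fat body markers (0.0107), because their added members were mostly higher. The same inclusion made calls, as higher, of insulin and TOR (2.81e-05), lipoproteins (1.90e-05), oxidative stress (2.38e-04), phagocytosis (2.17e-05) and melanization (9.44e-04). Other turns of direction, all of uncalled results, had causes that were not tested. For lipoproteins the adjusted p was 0.667 with the block, 0.659 unblocked and 0.347 to 0.954 with 1 library left out; for testis 0.831, 0.797 and 0.431 to 0.942; for lipid synthesis 0.703 to 0.880 and for lipolysis 0.225 to 0.969 with 1 library left out. Log2 fold changes that turned were numb, -0.141 to 0.0281 with 1 library left out (highest without infected replicate 1) and 0.00579 thinned; sls, 0.0170 by gene name; Acp36DE, -0.105 by gene name and -0.0679 to 0.284 with 1 library left out (lowest without infected replicate 1); and Mal-A1, -0.218 to 0.0348 with 1 library left out (above 0 without control replicate 5 or infected replicate 3). Depth, a median of 30 to 63 reads per gene and library, limits what can be called for genes with few reads.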

Other observations

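The 7 gene families and the genes named in this part were chosen after their values were seen. Serpins, inhibitors of serine proteases, rose in 9 of 23 tested members with none lower (median log2 fold change 0.56, camera adjusted p 1.02e-10, estimated correlation 0.0484). Spn88Eb averaged 426 ± 75.5 in control and 3473 ± 569 in infected libraries (log2 fold change 2.97, SE 0.18, adjusted p 3.60e-09). Spn43Ad averaged 187 ± 33.9 in control and 859 ± 311 in infected libraries (log2 fold change 2.03, SE 0.27, adjusted p 8.44e-05). The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, rose in 13 of 20 members with none lower (median 0.62, adjusted p 4.55e-13, estimated correlation 0.0484), among them LeuRS (log2 fold change 1.26, adjusted p 6.44e-04) and AspRS (log2 fold change 1.26, adjusted p 1.56e-05). Neprilysins and related genes, a family of metallopeptidases, rose in 11 of 24 members with none lower (median 0.60, adjusted p 1.59e-06), with Nep7 at 2.53 and Nepl6 at 1.97, but the family was not called with an estimated correlation (0.145). In 9 of the 11 neprilysins, 8 of the 13 synthetases and 6 of the 9 serpins, infected replicates 1 and 4 were both above infected replicates 3 and 5, where chance gives 16.7%. Nepl11 was at 10692 and 9923 against 3513 and 4946, and Nep6 at 3957 and 4028 against 1427 and 2098, which overlaps its control values. No member of these 3 families in the table held a value that was not whole reads.

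All 12 tested Jonah serine proteases, digestive enzymes of the gut, fell (median -1.59, adjusted p 2.63e-24, estimated correlation 0.015); 4 of them are also on the gut marker list. Jon25Biii averaged 8684 ± 1393 in control and 2768 ± 137 in infected libraries (log2 fold change -1.63, SE 0.14, adjusted p 3.19e-07). All 7 tested eggshell and yolk genes fell (median -2.04, adjusted p 1.41e-07), though not with an estimated correlation (0.0877), and the labels describe male flies. Their values varied among infected libraries, from 110 to 2736 for Yp1. Yp1, Yp2, Yp3, Cp15 and yl ranked infected replicates 1, 3, 4 and 5 in the same order, while Cp38 and dec did not. Infected replicates 1 and 4 were both above infected replicates 3 and 5 in 1 of 12 called Jonah genes and 0 of 7 called eggshell and yolk genes. Odorant-binding proteins fell in 3 of 24 members (median -0.44, adjusted p 5.07e-04; estimated correlation 0.202), and seminal fluid proteins fell in 3 of 21 and were not called as a family (median -0.08, adjusted p 0.116).

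The first principal component of the whole-read genes held 37.5% of the variance and separated the groups. On it infected replicates 1 and 4, higher in most called serpins, synthetases and neprilysins, lay at 33.9 and 35.0, infected replicates 3 and 5 at 14.0 and 14.2, and the control libraries between -26.2 and -21.2. The second held 17.0%, with infected replicate 3 at 37.0. Among genes with all 4 infected values off whole reads, the median variance over that of counting alone was 0.919 in infected libraries, in 142 genes, and 1.91 for the same genes in control libraries. Whole-read genes had 2.42 in infected and 2.92 in control libraries.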
